A study of Mus musculus with 5 samples.

How the data were processed

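The values analysed were the log2 signals that the authors deposited in the series matrix, 35556 probe sets on 5 arrays. RNA was extracted with a column kit, amplified and labelled with biotin, and hybridised to Affymetrix whole-transcript arrays, per the labels' protocols. Per the submitters' processing notes the software was Transcriptome Analysis Console 1.0.0.234 with the mm10 build. The background correction, the normalization, the summary of probes and the base of the logarithm are not given in the sources used here. The log2 scale was read from the values, which run from 0.727 to 13.9 with array medians between 5.90 and 6.02; if so, the authors deposited log2 signals. A scale with another base would change the fold changes but not the tests. Cultures were grown in medium with serum for fewer than 6 passages, per the labels' protocols, in a sentence that speaks of PDAC cells for every sample, and the series design speaks of cell lines.

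Probe sets were named from the platform annotation and matched by Entrez identifier to a reference list of mouse genes in the GRCm38.p6 assembly, the same assembly as mm10. Of the probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 had none here, and 21698 were matched to the reference, with 0 symbols changed. Probe sets with several symbols or none were left out of the gene tests. For the 999 genes with more than 1 probe set the probe set with the highest mean over the arrays was used, which left 19938 genes. Genes that the annotation used here does not list were not analysed here. The result of 1 of the gene lists is not reported here, though it is counted among the lists tested.

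Groups were taken from the titles and cell type labels: 2 normal ductal and 3 PDAC cultures. Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, testing both directions, with 3 residual and 0.91 prior degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fixed gene lists, 31 in all, were tested against all other genes with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated and with limma's fry. For each list the gene p-values were also adjusted over the list alone. Where a list with 0 calls over all genes is described, its members are named by their smallest p. The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Marker lists of photoreceptors, spermatids, striated muscle, Schwann, mast and mesothelial cells were added later, before the test that used them.

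By that rule the text names, among genes with an adjusted p under 0.05, groups that do not overlap, an ordinary gene symbol and a group mean above 6.61 (the median of all genes), the 12 with the largest rise and the 12 with the largest fall. It adds up to 4 members of each list in each direction past the threshold, or the 2 with the smallest p where a list has none, and Apc, Ctnnb1, Cdkn2a, Cdh1, Vim and Krt19. Other genes are said to have been named after their values were seen or stand as markers of a cell type.

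For each chromosome, the median difference of a PDAC array from the mean of the normal ductal arrays was taken over 9955 genes with a mean above the median, centred on the 19 autosomes. These steps and the figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. On simulated data made from the real means and spreads, with 200 changed genes in each of 20 runs over 19938 genes for this comparison, the gene test called 35.1% of genes changed by a log2 of 1, 64.4% of those changed by 2 and 84.5% of those changed by 4, and 5.4% of calls were false. A list shifted by 1 was called in 20 of 20 runs. How often a list with no shift is called was not measured. Means and spreads of genes hold no correlation between genes, so these runs do not check the preset correlation. A chromosome shift of 0.4 put into 1 array was found at a median of 0.399 in 20 runs.

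The alternatives were quantile normalization, a common array median, leaving out the lowest 25% or 50% of genes, no intensity trend, a robust variance model, the mean of all probe sets of a gene, array weights, the replicate number as a block, leaving out each culture in turn, all probe sets, other thresholds, no moderation of variances, and for chromosomes all genes or 1 normal ductal array as baseline. A fit without genes that have equal values within a group was added after seeing the data. The median log2 fold change of all genes was 0.01 as deposited, 0.04 after quantile normalization and 0.10 with arrays at a common median.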

Results

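RNA from 5 primary cultures of mouse pancreatic cells was hybridised to Affymetrix whole-transcript arrays, each array giving 1 log2 signal per probe set. In the genotypes the Pdx-1Cre transgene, which makes Cre recombinase in cells of the pancreatic lineage, was combined with a pair of floxed alleles that the labels write as p53L/L. The normal ductal group held 2 cultures with these alleles alone. The PDAC group held 3 cultures of pancreatic ductal adenocarcinoma cells that carried, in addition, 1 floxed allele of Apc, the gene of a scaffold protein that keeps beta-catenin low. The title of normal ductal replicate 2 left out Cre and the word ductal, while its other labels named ductal cells. The title of PDAC replicate 3 alone added the words mutant cell. Array medians lay between 5.90 and 6.02, and 19938 genes were tested. The labels call the samples biological replicates without naming separate animals, so p-values measured only the spread between these 5 cultures, and this small number limited the precision.

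The comparison of the PDAC cultures with the normal ductal cultures asked which genes separate tumour cells with a floxed Apc allele from duct cells that lack it. Igfbp4, a secreted binding protein of insulin-like growth factors, rose in PDAC, and 10 genes fell. The mean log2 signal of Igfbp4 was 7.11 ± 0.26 (SD, n = 2) in normal ductal and 10.62 ± 0.05 (SD, n = 3) in PDAC cultures, a fold of 11.4. The largest fall was that of Xirp2, an actin-binding protein best known from muscle, with a log2 fold change of -6.57 (SE 0.21) from 10.77 ± 0.28 (SD, n = 2) to 4.20 ± 0.24 (SD, n = 3). Il18r1, a chain of the interleukin-18 receptor, followed with -5.02 (SE 0.20), and Ildr1, a protein of tricellular junctions, with -3.94 (SE 0.09).

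The limma moderated test with Benjamini-Hochberg adjustment gave 11 genes with an adjusted p under 0.05. Adjusted p was 0.0419 for Igfbp4, 0.0386 for Xirp2, 0.0419 for Il18r1 and 0.0229 for Ildr1. The nucleoside transporter gene Slc28a3 (log2 fold change -3.40, adjusted p = 0.0418) and Dcdc2a, a gene of the primary cilium of duct cells (-3.29, adjusted p = 0.0229), fell as well. So did Muc16, which encodes the membrane mucin also known as CA125 (-2.67, adjusted p = 0.0170), Fam174b (-2.62, adjusted p = 0.0418) and Urah, an enzyme of urate breakdown (-1.38, adjusted p = 0.0418). Tox3 (-1.51) and Eps8l1 (-0.75), named after their values were seen, completed the 10. In the GRCm38 assembly Igfbp4 lies on chromosome 11 from 99040005 to 99052655, Xirp2 on chromosome 2 from 67446000 to 67526620, Ildr1 on chromosome 16 from 36693978 to 36726804 and Muc16 on chromosome 9 from 18495445 to 18674821.

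Before adjustment, 1296 genes were higher and 1367 lower in PDAC at p under 0.05. The arrays of the groups did not overlap for 5258 genes, 26.4% of those tested. By chance 20% would do so if no arrays held equal values. The chance share here is lower, since 721 genes had 1 value in all 5 arrays and could not part the groups. Scaling moved the balance of calls: quantile normalization gave 10 higher and 32 lower genes, and a common array median gave 23 higher and 57 lower. At an unadjusted p under 0.05 by limma the balance turned, with 1488 higher and 1405 lower under quantile normalization. With a common array median 1865 were higher and 1130 lower. Leaving out PDAC replicate 1, 2 or 3 left 0 higher and 0 lower genes by limma (955, 934 and 1416 higher and 994, 1061 and 1335 lower at an unadjusted p under 0.05), while the fits without normal ductal replicate 1 (980 higher, 307 lower) and without replicate 2 (125 higher, 865 lower) called more.

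**Figure D1:**
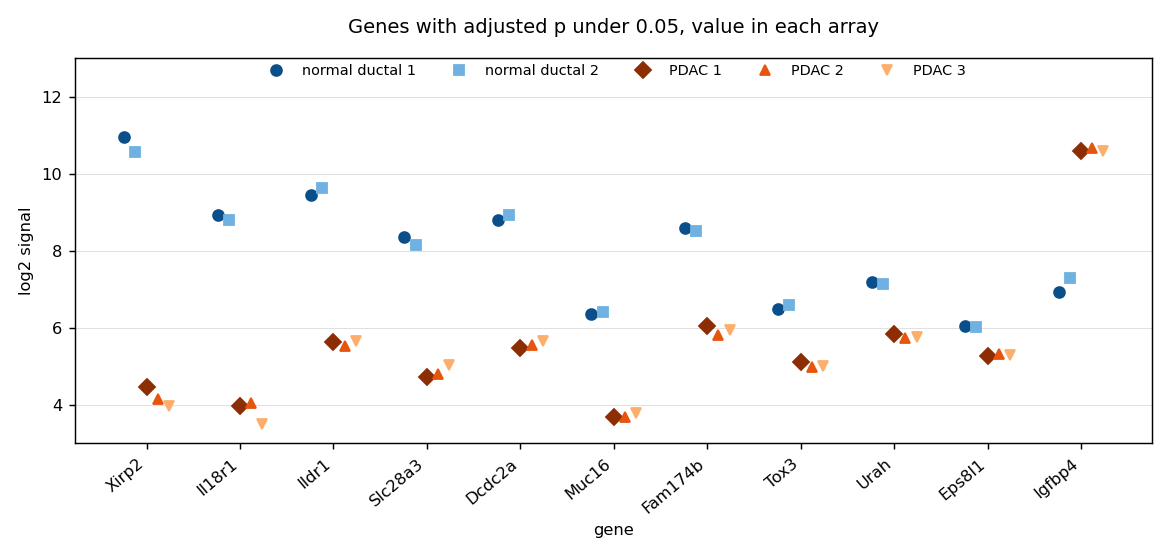
The log2 signal (vertical axis) of each of the 11 genes with an adjusted p under 0.05 (horizontal axis) is shown for each culture, 1 point per array, blue for normal ductal and red to orange for PDAC. Xirp2 lay at 10.96 and 10.57 in the normal ductal arrays and between 3.98 and 4.46 in the PDAC arrays, and only Igfbp4 was higher in PDAC.

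Epithelial genes formed the list with the largest difference. The 47 measured junction, keratin and epithelial transcription factor genes had a median log2 fold change of -3.02, and 42 of them were lower in every PDAC culture than in both normal ductal cultures. Adjusted over the list alone, 32 of the 47 fell, and over all genes tested limma called 0 (36 at an unadjusted p under 0.05). Among the 32 were Grhl2, a transcription factor of epithelial identity, with -2.53 (SE 0.20, adjusted p over the list 0.00466 and over all genes 0.119), and Ap1m2, which sorts proteins to the basolateral membrane, with -3.30 (SE 0.26, 0.00466 and 0.119). Also among them, and named after their values were seen, were the claudins Cldn4 (-4.76) and Cldn7 (-4.18), the membrane protease St14 (-4.86), the splicing factor Esrp1 (-4.60) and the adhesion molecule Epcam (-4.08).

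The PDAC cultures differed from each other in these genes. The list mean was 9.38 and 9.12 in normal ductal replicates 1 and 2, and 5.89, 6.23 and 7.47 in PDAC replicates 1, 2 and 3. E-cadherin (Cdh1) stood at 12.32 and 11.96 in normal ductal and at 6.41, 8.33 and 10.76 in PDAC cultures, a log2 fold change of -3.64 (SE 1.43) that did not pass the limma test (adjusted p = 0.418). The duct keratin Krt19 stood at 6.47, 9.51 and 11.74 in PDAC against 11.46 and 11.37 (-2.17, SE 1.73, adjusted p = 0.588). The list mean of fibroblast markers was 8.77, 8.25 and 8.15 in the PDAC replicates, 6.96 in normal ductal replicate 1 and 8.87 in replicate 2.

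The list shifted down by limma's camera test with a preset correlation (adjusted p = 1.07e-25), and the adjusted p = 0.589 with an estimated correlation, the highest over 16 alternatives, of which the lowest gave 7.37e-43. Without normal ductal replicate 1, 0 epithelial genes were called over the list alone, without normal ductal replicate 2 the count was 9, and without PDAC replicates 1 and 2 it was 18 and 9.

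Genes of the mesenchymal state shifted up. Of 28 measured genes, with a median log2 fold change of 0.72, the transcription factor Snai2 rose when adjusted over the list alone, with 2.93 (SE 0.31, adjusted p over the list 0.0225 and over all genes 0.148), and over all genes tested limma called 0 (6 higher at an unadjusted p under 0.05). Twist2, another transcription factor of this state, had 2.51 (SE 0.57, adjusted p = 0.243 over all genes). The intermediate filament gene Vim had 0.80 (SE 0.27, adjusted p = 0.356). Camera gave an adjusted p = 0.0117, and adjusted p = 0.706 with an estimated correlation (8.75e-06 to 0.706 over 16 alternatives). The list mean was 9.18 in normal ductal replicate 1, 10.21 in replicate 2 and between 10.05 and 10.75 in the PDAC cultures, and without replicate 1 the adjusted p was 0.491.

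Fibroblast and stellate cell markers did not shift as a list (27 measured, median log2 fold change 0.37, adjusted p = 0.319). The collagen VI genes Col6a1 and Col6a2 rose when adjusted over the list alone (adjusted p 0.00193 and 0.00676), with log2 fold changes of 3.23 (SE 0.18) and 2.22 (SE 0.21), and over all genes tested limma called 0 of the list (2 higher and 1 lower at an unadjusted p under 0.05). Both stood low in the 2 normal ductal cultures, Col6a1 at 6.88 and 7.10. Most other markers were high in normal ductal replicate 2: 19 of the 27 lay more than 1 above replicate 1, among them Dcn at 11.39 against 7.58 and Pdgfra at 9.65 against 6.63. Without replicate 2 the fibroblast list shifted up (adjusted p = 0.00173, with 0.00173 to 0.827 over 16 alternatives).

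Cell cycle genes shifted up. The 44 measured genes had a median log2 fold change of 0.56, and 36 were higher in every PDAC culture than in both normal ductal cultures. When adjusted over the list alone, 12 rose, and over all genes tested limma called 0 (25 at an unadjusted p under 0.05). Tk1, the thymidine kinase of S phase, had 1.49 (SE 0.13, adjusted p over the list 0.0179 and over all genes 0.136), and Mcm7, a subunit of the replicative helicase, 0.76 (SE 0.09, 0.0185 and 0.149). The list mean was 9.45 and 9.27 in normal ductal and 9.85, 10.00 and 9.90 in PDAC cultures. Camera gave an adjusted p = 1.69e-13, and adjusted p = 0.539 with an estimated correlation (2.46e-14 to 0.539 over 16 alternatives). Fibroblast markers, by contrast, had list means of 6.96 and 8.87 in normal ductal and 8.15 to 8.77 in PDAC cultures. Over the list alone the count was 27 with arrays at a common median and between 0 and 2 with any 1 culture left out.

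Sterol and fatty acid synthesis genes shifted up as well (27 measured, median log2 fold change 0.41, camera adjusted p = 0.000491, adjusted p = 0.706 with an estimated correlation, 7.20e-07 to 0.706 over 16 alternatives). Limma called 0 of them adjusted over the list alone and 0 over all genes tested, with 6 higher at an unadjusted p under 0.05. Elovl6, which lengthens fatty acids, had 1.29 (SE 0.26, adjusted p = 0.217), and Acaca, the first enzyme of fatty acid synthesis, 0.47 (SE 0.10, adjusted p = 0.218). The list mean was highest in PDAC replicate 3, at 10.45, against 9.74 and 9.50 in the other PDAC cultures and 9.41 and 9.18 in normal ductal cultures.

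Duct and pancreatic progenitor genes shifted down (31 measured, median log2 fold change -0.50). Dcdc2a fell over all genes tested, and adjusted over the list alone it remained the 1 gene that fell. The list mean was 7.95 and 7.93 in normal ductal and 6.39, 6.99 and 7.79 in PDAC cultures. Camera gave an adjusted p = 0.00359, and adjusted p = 0.706 with an estimated correlation (3.18e-06 to 0.706 over 16 alternatives). Mucins and gastric-type genes (30 measured, median -0.04) shifted down with an adjusted p = 0.0471, and adjusted p = 0.706 with an estimated correlation (0.00364 to 0.706 over 16 alternatives, under 0.05 in 7). The call ended under quantile normalization (0.141) and without PDAC replicate 1 (0.170) or 2 (0.162), and the list mean was 5.77 and 6.00 in normal ductal and 4.88, 5.42 and 5.94 in PDAC cultures, replicate 3 lying among the normal ductal values. Muc16 fell over all genes tested. With p adjusted over the list alone, Muc16, the adhesion molecule Ceacam1 (-5.58, SE 0.72) and the mucin Muc4 (-0.33, SE 0.05) fell, 3 in all, with Ceacam1 and Muc4 named after their values were seen.

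Growth factor and MAPK feedback genes shifted down (37 measured, median log2 fold change -0.22, camera adjusted p = 0.0376, adjusted p = 0.539 with an estimated correlation, 0.00102 to 0.753 over 16 alternatives). List means were 8.13 and 8.22 in normal ductal and 7.92, 7.97 and 7.86 in PDAC cultures, and Igfbp4, a member of this list, went the other way. The gene test adjusted over the list alone gave 1 that rose and 2 that fell, the latter being Pdgfb, a platelet-derived growth factor (-3.56, SE 0.52), and the receptor Erbb3 (-3.27, SE 0.51), both named after their values were seen. Over all genes tested, 1 rose and 0 fell. Immediate early genes, which respond to the handling of cultures, shifted down as well (28 measured, median -0.52, adjusted p = 0.00111, adjusted p = 0.589 with an estimated correlation, 7.23e-06 to 0.589 over 16 alternatives), with list means of 8.54 and 8.79 in normal ductal and 8.39, 8.21 and 7.86 in PDAC cultures. Limma called 0 adjusted over the list alone and 0 over all genes tested, with 8 lower at an unadjusted p under 0.05. Csrnp1 had -0.98 (SE 0.17, adjusted p = 0.199) and Klf6 -1.12 (SE 0.21, adjusted p = 0.208).

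Cytokine genes (43 measured, median log2 fold change -0.32) shifted down with an adjusted p = 0.0444, and adjusted p = 0.539 with an estimated correlation (0.000495 to 0.655 over 16 alternatives, under 0.05 in 10). List means were 6.85 and 7.28 in normal ductal and 6.61, 6.42 and 6.81 in PDAC cultures, 15 of the 43 lay more than 1 higher in normal ductal replicate 2 than in replicate 1, and without replicate 2 the call ended (0.655). Of the cytokine genes, limma called 0 adjusted over the list alone and 0 over all genes, with 2 higher and 7 lower at an unadjusted p under 0.05. Csf2, the growth factor GM-CSF, had -2.33 (SE 0.29, adjusted p = 0.162), and Lif, a cytokine of the interleukin-6 family, -2.46 (SE 0.47, adjusted p = 0.210). Interferon response genes (33 measured, median -0.09) shifted down with an adjusted p = 0.0127, and adjusted p = 0.706 with an estimated correlation (0.00133 to 0.706 over 16 alternatives), with list means of 6.52 and 6.23 in normal ductal and 6.32, 5.91 and 6.07 in PDAC cultures. The only gene that fell adjusted over the list alone was Cxcl11, which the annotation used here gives as a transcribed pseudogene (-1.53, SE 0.11, adjusted p over the list 0.00563 and over all genes 0.119), and over all genes tested limma called 0 (6 lower at an unadjusted p under 0.05). Ifih1, a sensor of viral RNA, had -1.29 (SE 0.31, adjusted p = 0.262). Antigen presentation genes (17 measured) had an adjusted p = 0.0652, which lay under 0.05 in 7 of 16 alternatives (0.0124 to 0.747), with 1 that fell adjusted over the list alone, the class II gene H2-Ab1 (-1.83, SE 0.25), and 0 over all genes (3 lower at an unadjusted p under 0.05). H2-Q4 had -2.54 (SE 0.69, adjusted p = 0.295).

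Markers of acinar cells (median log2 fold change -0.64, camera adjusted p = 0.000505), islet cells (-0.58, 0.000304), endothelial cells (-0.23, 0.000505) and leukocytes (-0.15, 0.00279) shifted down in PDAC as lists. With an estimated correlation the adjusted p = 0.706, 0.645, 0.589 and 0.539 in that order. Limma called 0 genes of these lists adjusted over the list alone and 0 over all genes tested, with 2, 3, 4 and 1 lower at an unadjusted p under 0.05 in the acinar, islet, endothelial and leukocyte lists. Many of the acinar, islet and endothelial markers stood higher in normal ductal replicate 2. The chymotrypsinogen gene Ctrb1 was at 12.26 there and at 6.08 in replicate 1, glucagon (Gcg) at 10.22 against 7.33 and the endothelial mucin-like gene Emcn at 8.86 against 6.21. The leukocyte markers hardly differed between these arrays (median difference 0.07, 4 of 31 over 1), with lysozyme (Lyz2) at 8.52 in replicate 2 and 5.67 in replicate 1. Of the members with the smallest p, the acinar regulator Nr5a2 had -1.45 (SE 0.37) and Amy1 -0.58 (SE 0.16), the islet factor Nkx2-2 -0.92 (SE 0.14), the lymphatic factor Prox1 -1.21 (SE 0.26), Mmrn2 -0.15 (SE 0.03) and the receptor Cd14 -2.78 (SE 0.72).

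Without normal ductal replicate 2, 6 of the 15 lists that shifted still did. The calls of the acinar (adjusted p = 0.524), islet (0.0740), endothelial (0.157) and leukocyte lists (0.0863) ended. So did those of the duct (0.310), growth factor (0.753), cytokine (0.655) and immediate early lists (0.284), and the same replicate held the high marker levels given above. Over 16 alternatives the adjusted p ran from 2.52e-15 to 0.999 for the acinar, 5.61e-12 to 0.645 for the islet, 3.67e-10 to 0.900 for the endothelial and 0.000343 to 0.539 for the leukocyte list. The epithelial, cell cycle, sterol, mesenchymal, interferon and gastric-type lists stayed past the threshold. Of all 16 alternatives, 14 kept the call of the epithelial, cell cycle and sterol lists, 13 that of the immediate early list, 12 those of the acinar, islet, endothelial and leukocyte lists, 11 those of the duct and mesenchymal lists, 10 those of the cytokine and interferon lists, 9 that of the growth factor list and 7 that of the gastric-type list. The 2 that ended the call of the epithelial, cell cycle and sterol lists were the estimated correlation and fry. The other 14 all kept the preset correlation of 0.01. The correlation estimated from these arrays was 0.663 in the epithelial, 0.215 in the cell cycle and 0.686 in the sterol list. In the leukocyte, growth factor and cytokine lists it was 0.011, 0.001 and -0.006, and their calls ended too. Their unadjusted camera p went from 0.000809 to 0.0452, from 0.01575 to 0.0685 and from 0.0200 to 0.0695. The size of the correlation thus does not by itself account for the calls that ended with an estimated correlation.

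**Figure D2:**
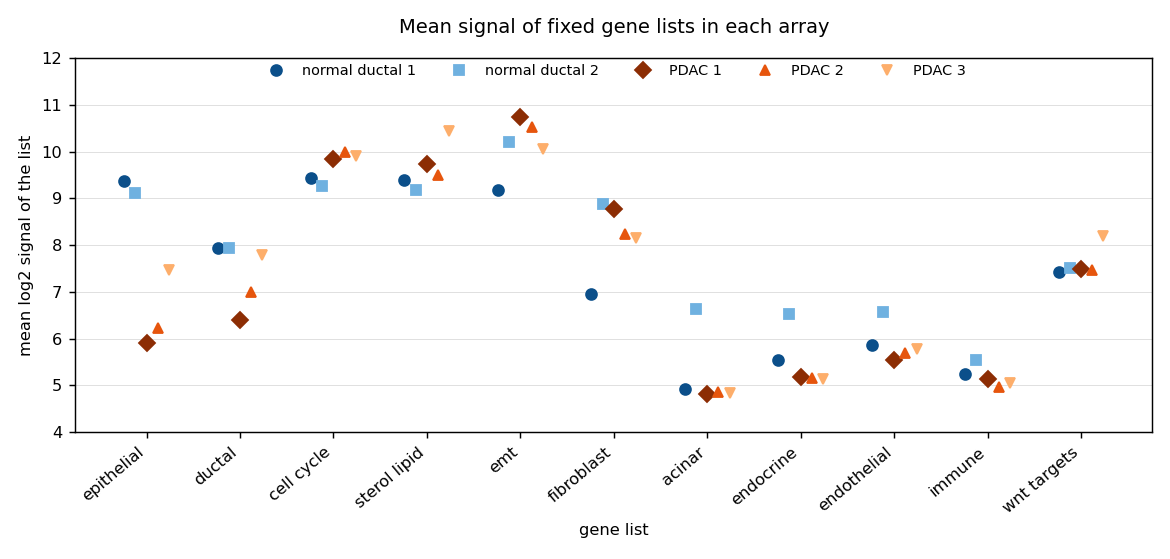
The mean log2 signal (vertical axis) of 11 gene lists (horizontal axis) is shown for each culture, 1 point per array, blue for normal ductal and red to orange for PDAC. Epithelial genes were at 9.38 and 9.12 in normal ductal and between 5.89 and 7.47 in PDAC cultures, and acinar markers were at 6.62 in normal ductal replicate 2 and between 4.80 and 4.92 in the other arrays.

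Wnt target genes did not shift between the groups. The 26 measured had a median log2 fold change of 0.22 (camera adjusted p = 0.319). Limma called 0 adjusted over the list alone and 0 over all genes tested, with 3 higher and 1 lower at an unadjusted p under 0.05. Cd44, an adhesion receptor, had -0.96 (SE 0.22, adjusted p = 0.251), and Porcn, an enzyme that lipidates Wnt proteins, 1.15 (SE 0.32, adjusted p = 0.297). The list mean was 8.20 in PDAC replicate 3 and between 7.42 and 7.50 in the other 4 arrays. Mesothelial markers also had their highest mean in PDAC replicate 3, at 7.45, against 5.51 to 6.84 elsewhere. Wnt ligands, receptors and antagonists had a median of -0.01 over 46 genes (adjusted p = 0.750), and the direction of the list turned under quantile normalization. The single gene (1) that fell adjusted over the list alone was the ligand gene Wnt11 (-1.41, SE 0.09, adjusted p over the list 0.00629 and over all genes 0.102), and over all genes tested 0 fell (3 higher and 5 lower at an unadjusted p under 0.05). Wnt7a had -3.59 (SE 0.82, adjusted p = 0.245).

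Apc itself did not differ (log2 fold change -0.25, SE 0.20, adjusted p = 0.590). It was at 9.23 and 9.02 in normal ductal and between 8.58 and 9.06 in PDAC cultures, with a 95% interval of the difference from -0.80 to 0.31. Its gene lies on chromosome 18 from 34220297 to 34322190 in GRCm38. A gene-level probe set averages over exons in and outside a floxed part, so this level checks the genotype only in a limited way. Beta-catenin (Ctnnb1) had -0.47 (SE 0.22, adjusted p = 0.497). The tumour suppressor gene Cdkn2a had 2.35 (SE 1.08, adjusted p = 0.491), with 10.34 and 7.13 in normal ductal and between 10.71 and 11.46 in PDAC cultures.

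The list of genes altered in pancreatic cancer did not shift (27 measured, median log2 fold change -0.08, adjusted p = 0.349), and limma called 0 over the list alone and over all genes, with 2 higher and 3 lower at an unadjusted p under 0.05. Its members of smallest p were the apoptosis inhibitor Birc3 (-1.34, SE 0.31, adjusted p = 0.251) and Mdm2 (-1.08, SE 0.29, adjusted p = 0.293). Notch and hedgehog genes had a median of 0.01 (33 measured, adjusted p = 0.952). There, adjusted over the list alone, Gas1, a hedgehog co-receptor, rose (2.13, SE 0.13), while Jag1, a Notch ligand, (-2.15, SE 0.23) and the receptor Notch1 (-0.84, SE 0.14), named after its values were seen, fell, with 0 over all genes tested. The direction of that list turned with arrays at a common median. TGF-beta and BMP genes (41 measured, adjusted p = 0.913) had a median of -0.06 and a mean of 0.20, while the camera test pointed down and fry up. Limma called 0 genes of it adjusted over the list alone and 0 over all genes, with 4 higher and 4 lower at an unadjusted p under 0.05. The BMP antagonist Grem1 had 3.32 (SE 0.50, adjusted p = 0.173) and Tgfbi, a matrix protein, 3.61 (SE 0.75, adjusted p = 0.222).

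Basement membrane and integrin genes (35 measured, median log2 fold change -0.25, adjusted p = 0.149) held genes of both directions, and the list shifted down with arrays at a common median (0.00679) and without PDAC replicate 1 (0.0142). With p adjusted over the list alone, 3 rose and 2 fell, and over all genes tested 0 did (4 higher and 8 lower at an unadjusted p under 0.05). Those that rose were the integrin chains Itgb5 (1.11, SE 0.12) and Itgb8 (1.43, SE 0.18) and the laminin chain Lamb2 (1.06, SE 0.16), and those that fell were Lama3 (-1.95, SE 0.32) and Itga2 (-4.59, SE 0.89). Lamb2, Lama3 and Itga2 were named after their values were seen. Matrix protease genes had an adjusted p = 0.319 (34 measured), with 0.0153 for arrays at a common median and 0.00602 without normal ductal replicate 1, and limma called 0 adjusted over the list alone and 0 over all genes, with 1 higher and 4 lower at an unadjusted p under 0.05. Serpinb2, a plasminogen activator inhibitor, had -3.32 (SE 0.59, adjusted p = 0.198), and the cathepsin gene Ctsl -0.98 (SE 0.23, adjusted p = 0.258). Glycolysis and hypoxia genes had an adjusted p = 0.273 (36 measured), and 0.0385 without normal ductal replicate 2. Muscle-type phosphofructokinase (Pfkm, 1.67, SE 0.14) was the 1 gene that rose adjusted over the list alone, and over all genes 0 did (4 higher and 4 lower at an unadjusted p under 0.05). The glucose transporter Slc2a1 averaged 11.85 in normal ductal and 10.85 in PDAC cultures (adjusted p = 0.173).

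Antioxidant and glutathione genes had an adjusted p = 0.632 (33 measured), and 0.0360 without normal ductal replicate 1. In it 3 fell adjusted over the list alone, the glutathione peroxidase genes Gpx2 (-1.80, SE 0.15) and Gpx3 (-2.79, SE 0.40) and the transferase gene Gstt2 (-0.89, SE 0.10), with 0 over all genes tested and 6 higher and 4 lower at an unadjusted p under 0.05. Gpx3 was named after its values were seen. The unfolded protein response list (31 measured, adjusted p = 0.750) had a median of 0.07, a mean of -0.03 and a camera direction up, which turned under quantile normalization and a common median. The 2 that fell adjusted over the list alone were the phosphatase subunit Ppp1r15a (-0.85, SE 0.11) and the stress gene Ddit4 (-1.27, SE 0.19), with 0 over all genes and 3 higher and 4 lower at an unadjusted p under 0.05. Hox genes (37 measured, adjusted p = 0.690), with Hoxb5 at -0.88 (SE 0.43) and Hoxc13 at -0.32 (SE 0.18), did not shift. Ovarian-type stroma genes (12 measured, adjusted p = 0.716) had a median of 0.01, a mean of -0.02 and a camera direction down, which turned under quantile normalization. Their members of smallest p, Cyp11a1 and Star, each had -0.35 (SE 0.10 and 0.13). Limma called 0 genes of the Hox and ovarian-type lists adjusted over the list alone and over all genes, with 0 and 1 at an unadjusted p under 0.05. Housekeeping genes, read as a check of scale, had a median of 0.11 (21 measured, adjusted p = 0.319), and limma called 0 over the list alone and over all genes, with 3 higher and 2 lower at an unadjusted p under 0.05. Tbp had 0.70 (SE 0.11, adjusted p = 0.173) and Eef2 -0.16 (SE 0.04, adjusted p = 0.288). Genes that mark the sex of the mouse (8 measured, adjusted p = 0.878, 0 genes at an unadjusted p under 0.05) differed between PDAC cultures. Xist, the RNA of the inactive X chromosome, was at 10.55 and 10.46 in normal ductal and at 10.77, 7.67 and 3.71 in PDAC replicates 1, 2 and 3, and the Y-linked gene Kdm5d was at 4.76 in PDAC replicate 3 and at 3.74 or below elsewhere. The sex of the mice may thus differ between cultures, which the comparison of the groups did not take into account.

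**Figure D3:**
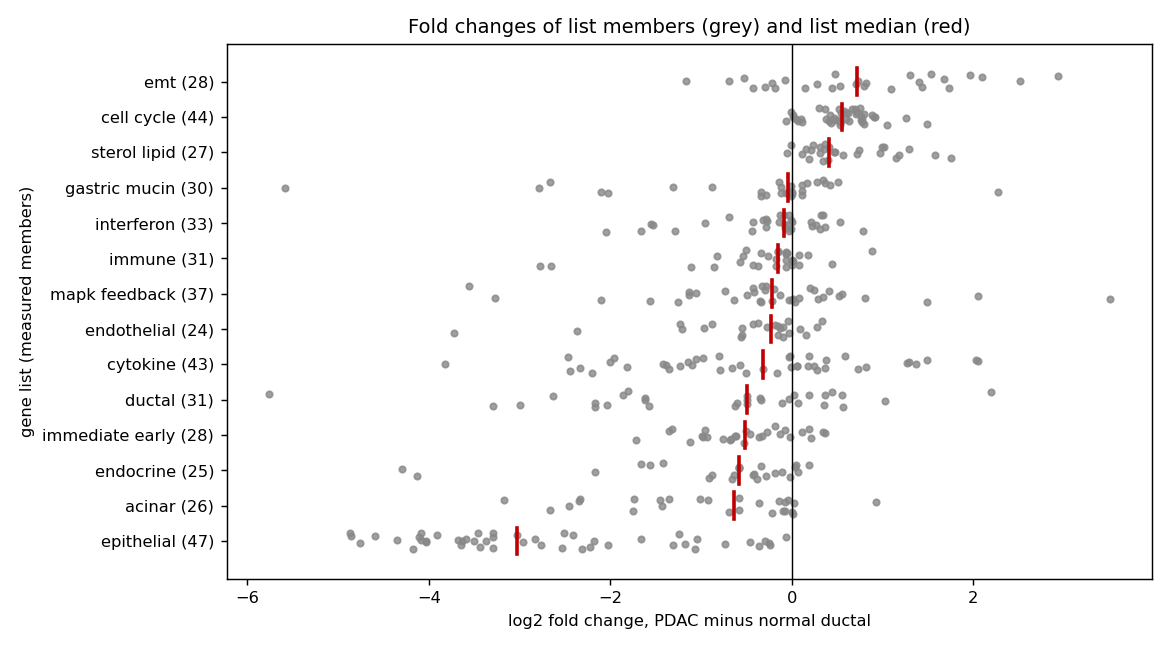
The log2 fold change of PDAC over normal ductal (horizontal axis) is shown for each measured member (grey points) of 14 lists with a camera adjusted p under 0.05 (vertical axis, number of members in brackets), with the list median in red. The epithelial list has the lowest median, at -3.02, and the mesenchymal list (emt) the highest, at 0.72.

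With the correlation between genes estimated from these arrays, 0 of the 31 lists kept an adjusted p under 0.05, and limma's fry test, which asks whether a list moves on balance in 1 direction, also called 0. Fry gave an adjusted p = 0.129 for both the epithelial and the cell cycle list.

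Arrays of 1 group resembled each other more than arrays of different groups. The Pearson correlation over all genes was 0.980 between the normal ductal arrays, 0.970 to 0.983 between the PDAC arrays, and 0.946 to 0.961 between groups. The first principal component held 54.7% of the variance and parted the groups. On it PDAC replicate 3, the PDAC culture with the highest epithelial list mean, lay nearest to the normal ductal arrays. No 2 arrays held the same values throughout, but 9521 genes (47.8%) had equal values in at least 2 arrays, 78.9% of genes with a mean signal under 6 and 17.1% of those over 8. Equal values shrink the spread of the genes that hold them, and these spreads enter the variance model of all genes. In a fit chosen after seeing the data, without the 7444 genes with equal values within a group, 36 genes rose and 131 fell, which included Igfbp4 and 9 of the 10 genes that fell above. The prior degrees of freedom were 2.39 in that fit, against 0.91 with all genes. Over all genes left in it, 13 of 45 epithelial genes measured fell, where the first fit called 0 of that list.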

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

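The fit without genes that have equal values within a group was chosen after seeing the data, and the other alternatives were planned. Over the alternatives, the fold changes of named genes kept their direction in every case run (988 on the same side of the threshold, 61 newly past it, 52 no longer past it), and the list tests kept theirs in 382, 14 and 66 cases, while 34 turned, all among lists not called. Of the 9 named genes past the threshold, 9 stayed past it under quantile normalization, a common median, the mean of all probe sets and no intensity trend. With a robust variance model 8 did, with array weights 3, and with no moderation, the replicate block, or without any PDAC replicate 0. The fits without a normal ductal replicate leave a lone array in that group, and most of their calls rest on a spread of 0. They are left out of these counts of the 9 named genes. The number of arrays limits the precision. Except where stated, the cause was not tested.

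Genes higher and lower in PDAC numbered 10 and 32 under quantile normalization, and 23 and 57 with arrays at a common median (27 cell cycle genes higher, adjusted over the list alone). Without the lowest 25% of genes 3 were higher, and without the lowest 50% 15 were higher and 27 lower, with 8 lists called. Array weights gave 0 higher and 3 lower, with 3 cell cycle genes. All probe sets gave 0 and 1, an adjusted p under 0.10 gave 6 and 19, and an unadjusted p under 0.05 with a log2 fold change of at least 1 gave 286 and 567, these thresholds differing by construction. With no moderation of variances 0 were lower (998 at an unadjusted p under 0.05), with 19 epithelial and 3 cell cycle genes. Without genes with equal values there were 36 higher and 131 lower. With an estimated correlation 0 lists were called, with 0.589 for the epithelial and 0.539 for the cell cycle list, and with fry 0, with 0.129 for both.

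With the replicate block, limma called 0 genes higher, 0 lower and 0 cell cycle genes (1104 higher and 1110 lower at an unadjusted p under 0.05). That the number was not taken as a pairing was fixed before the data were examined. The arrays sharing a replicate number did not resemble each other, since their deviations from the group means had correlations across genes of -0.178 and -0.042. With 2 normal ductal arrays, whose deviations mirror each other, these correlations are a limited check.

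Leaving out 1 culture gave 0 to 980 higher and 0 to 865 lower genes, 0 to 40 epithelial and 0 to 2 cell cycle genes, and 8 to 15 lists called. A lone normal ductal array is assumed to vary like the PDAC arrays. Without normal ductal replicate 1, 804 of 1287 calls had 1 value in all 3 PDAC arrays, and without replicate 2, 660 of 990 did, so most of these calls rest on a spread of 0.

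The direction of these lists turned, with the adjusted p given. Under quantile normalization these were Wnt ligands and receptors (0.990), ovarian-type stroma (0.990) and unfolded protein response (0.792). With arrays at a common median they were Notch and hedgehog (0.685), unfolded protein response (0.821) and sex-linked genes (0.889). Without the lowest 25% of genes it was Notch and hedgehog (0.943), and without the lowest 50% Notch and hedgehog (0.963), unfolded protein response (0.963) and Hox (0.630). Array weights turned TGF-beta and BMP (0.975), and the replicate block Wnt targets (0.785) and Notch and hedgehog (0.753). When 1 culture was left out, the adjusted p of lists that turned in at least 1 such fit ran as follows. Without normal ductal replicate 1 the fibroblast (0.00173 to 0.646), glycolysis (0.0385 to 0.768) and Hox lists (0.0863 to 0.797) turned, without normal ductal replicate 2 the matrix protease list (0.00602 to 0.457), and without PDAC replicate 1 ovarian-type stroma (0.304 to 0.993). Without normal ductal replicate 1 and without PDAC replicate 3, Wnt targets turned (0.116 to 0.954), and without normal ductal replicate 1 and without PDAC replicate 2, the unfolded protein response (0.237 to 0.955). Wnt ligands (0.398 to 0.939) and TGF-beta and BMP (0.383 to 0.989) turned without normal ductal replicate 2 and without PDAC replicate 2. Without normal ductal replicate 2 and without PDAC replicate 1, antioxidant (0.0360 to 0.832) and sex-linked genes (0.524 to 0.981) did, and without PDAC replicate 1 and without PDAC replicate 3, Notch and hedgehog (0.659 to 0.944). TGF-beta and BMP also turned without genes with equal values (0.896) and with fry (0.839).

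In 14 cases a list not called in the first fit passed the threshold. Antigen presentation did so with arrays at a common median (adjusted p 0.0216), the mean of all probe sets (0.0470), array weights (0.0356), the replicate block (0.0124), without PDAC replicate 1 (0.0481), without PDAC replicate 3 (0.0325) and without genes with equal values (0.0497). Basement membrane and integrin genes did with a common median (0.00679) and without PDAC replicate 1 (0.0142), matrix proteases with a common median (0.0153) and without normal ductal replicate 1 (0.00602), antioxidant genes without that replicate (0.0360), and fibroblast (0.00173) and glycolysis genes (0.0385) without normal ductal replicate 2.

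The robust variance model was not run for the list tests, since camera has no such option.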

Other observations

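The test of fibroblast markers was chosen after its result was seen, and the patterns were noticed in the same data that tested them. Single PDAC cultures stood apart in some members of the lists tested. In PDAC replicate 3 the Wnt feedback genes Axin2, Lgr5 and Rnf43 were at 8.42, 9.17 and 8.46, against at most 6.56, 5.67 and 6.69 in the other arrays, and Cldn18 and Vsig1, genes of gastric epithelium, were at 10.70 and 9.26. Of 26 Wnt target genes, 11 were highest in that culture and 4 of these by more than 1, while the feedback genes Nkd1 (7.68), Notum (6.67) and Znrf3 (8.22) were not set apart, with 7.75, 6.66 and 8.32 in another PDAC array. The mean of mesothelial markers was 7.45 in PDAC replicate 3, 5.58 and 5.51 in replicates 1 and 2, and 6.33 and 6.84 in normal ductal cultures. The secreted Wnt antagonist Sfrp2 was at 12.87 and 11.60 in PDAC replicates 1 and 2, and at 6.81 in replicate 3 and 6.44 and 6.12 in normal ductal cultures. These genes were named after their values were seen.

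Markers of acinar, islet and endothelial cells were higher in normal ductal replicate 2 than in replicate 1 (median difference 1.12, 0.77 and 0.41, with 14 of 26, 9 of 25 and 7 of 24 over 1), and leukocyte markers hardly so (0.07, 4 of 31). The abundant acinar genes Ctrb1, Cpa1 and Reg1 were at 12.26, 10.12 and 9.36 in replicate 2 and at 6.08, 5.54 and 4.41 in replicate 1, Iapp and Ins2 at 10.34 and 9.21 against 6.77 and 6.10, and Cdh5 at 8.87 against 6.47, while Cela2a (6.17 and 5.89) and Ptf1a (4.71 and 4.71) stayed near the floor. A scale difference of dim genes is argued against by 10000 random lists matched on level, of which 0 reached the median of the 4 lists pooled (0.51). This is given as a share of 0.0001, the smallest they can give. The highest random median was 0.0, and many dim genes have equal values in at least 2 arrays. Any list with a median above 0.0 would thus give this share, which does not measure the size of the difference. Remaining acinar, islet and endothelial cells are a candidate source, which the leukocyte list leaves open for leukocytes, since 34 of 106 members lay more than 1 higher in replicate 2, and the median difference was -0.10, -0.03 and -0.18 in lists of absent tissues (photoreceptor, spermatid, striated muscle). Of other cells the pancreas holds, fibroblast markers were higher as well (2.24, 19 of 27 over 1), 4 of 12 mesothelial markers lay over 1 higher (median 0.01), and the median was -0.20 and 0.00 for Schwann and mast cells. The prediction for remaining cells was set before its test and was met. The marker lists had already been seen to be high in this array, so that part of the prediction largely restated the pattern. Only the lists of absent tissues were new to it, and these stood low, with means between 4.54 and 5.57 in the normal ductal arrays. Marker levels cannot tell such cells from another kind of culture, which stays open, since the title of replicate 2 leaves out Cre and ductal.

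Epithelial genes were low in the PDAC cultures. Another scaling of the arrays is argued against by the count adjusted over the list alone, which was 32 as deposited and at least 37 under quantile normalization and a common median. Fewer epithelial cells and more fibroblasts in the PDAC cultures cannot be told apart from a change within the tumour cells. In PDAC replicates 1, 2 and 3, 11, 17 and 18 of 27 fibroblast markers lay at or below normal ductal replicate 2. That culture was itself high in these markers, with 19 of 27 more than 1 above normal ductal replicate 1. Above normal ductal replicate 1 lay 21, 19 and 17, and above both normal ductal arrays 15, 9 and 8. Mesenchymal tumour cells share many of these markers, which keeps the question open. The genotype and the tumour state, which the design names, stay open as untested.

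Genes of whole chromosomes shifted together in single PDAC cultures. The median log2 difference of chromosome 3 from the normal ductal mean was 0.40 in PDAC replicate 2, against 0.09 and -0.03 in replicates 1 and 3, and that of chromosome 12 was -0.27 in replicate 3, against 0.18 and 0.15, with at most 0.07 between the normal ductal arrays. A scale difference by level is argued against, since 0 of 10000 matched gene sets reached either shift, given as a share of 0.0001, the smallest they can give. Gain or loss of chromosome copies is a candidate explanation, since each part of the chromosome by position kept at least 0.877 of the shift, though with all genes in place of expressed ones the shifts of chromosomes 3 and 12 were 0.15 and -0.11. That each part of the chromosome keeps the shift was the prediction for gain or loss of copies, set before its test. No copy number was measured, so gain or loss of copies stays a candidate.

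Chromosome 15 was higher in all 3 PDAC cultures (0.40, 0.28 and 0.23), chromosome 17 as well (0.22, 0.14 and 0.27), and chromosomes 7 (-0.34, -0.24 and -0.19) and 18 (-0.13, -0.10 and -0.25) were lower, as values with no test. Chromosome 18, on which Apc lies, was not set apart in replicates 1 and 2. Chromosome 9 was at -0.12 in replicate 1, chromosome 1 at -0.18 in replicate 2, and chromosome 10 at -0.11, -0.11 and -0.04. Chromosome X was higher in all 3 (0.07, 0.21 and 0.21). With all genes in place of expressed ones, the shifts of PDAC replicates 1, 2 and 3 were 0.13, 0.10 and 0.09 on chromosome 15, 0.06, 0.05 and 0.10 on chromosome 17, -0.06, -0.04 and -0.04 on chromosome 7, and -0.01, -0.01 and -0.06 on chromosome 18. On chromosomes 3 and 12 the other replicates then had 0.02 and 0.00, and 0.05 and 0.06. With normal ductal replicate 1 or 2 alone as baseline, the shift of PDAC replicate 3 on chromosome 15 was 0.17 or 0.30, and that of PDAC replicate 1 on chromosome 18 was -0.07 or -0.08. Over the 3 alternatives, 24 of the recomputed values for chromosomes 3, 7, 12, 15, 17 and 18 moved and 30 did not.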
